A study of Mus musculus with 4 samples.

How the data were processed

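The data are 4 RNA-seq libraries from mouse brain, 2 labelled excitatory (αCaMKII-positive) and 2 labelled inhibitory (vGAT-positive). Per the labels' protocols, fluorescent cells were collected by hand with a glass pipette, 100 per library, and lysed for cDNA synthesis with the SMART-seq v4 kit, after which libraries were made with the Nextera XT kit. Neither kit is described as marking strand, so reads of overlapping antisense genes cannot be told apart.

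The authors' deposited tables hold 1 value per gene and library for 24421 genes on a log2 scale. Per the submitters' processing notes, TopHat and edgeR were used with the genome build mm10; the notes give no versions, roles or order, and the counting tool and annotation are not given in the sources used here. The log base and the added 1 were settled from the values: the low values fall into bands that are evenly spaced after 2 to the power of the value minus 1 (spacing varied by 0.209% to 1.91%), and not with a natural base (20.2% to 26.8%). The spacing was 1.28, 1.22, 0.72 and 0.873 in excitatory 1, excitatory 2, inhibitory 1 and inhibitory 2, so the authors scaled reads differently in each library. The values on the linear scale sum to 80200000, 77500000, 53400000 and 54400000, which divided by the spacing gives about 62800000, 63600000, 74200000 and 62300000 reads, as an estimate. No interval for counting error was computed, since the reads were only estimated. The estimated reads served the sampling check described below. Exact zeros were taken as listed; for genes at 0 in both libraries of a group the values of each library are given without a fold.

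The tests planned before the data were examined were written for raw counts or, if the tables held normalized values, for limma on the log2 values; since the tables hold log2 values, the second plan was used and count models were not run. In R 4.3.3, limma 3.58.1 fitted the difference between the labels with a mean-variance trend to 13619 genes with a value of at least 1 in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 2.56 and the residual 2 degrees of freedom. Of all genes, 9583 were at 0 in every library. Gene lists were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative) and fry, for lists with at least 3 tested members, with adjustment over the 25 lists tested. Of 27 lists fixed before the data were examined, the list of other transmitter neurons had too few tested members, and none of the 13 mitochondrially encoded genes is in the tables used here (0 of 13). Symbols were matched to GENCODE release M21, on the same build as mm10, for 23334 genes (95.5%). Of 10097 genes with a mean of at least 5, 93 had the same 4 values as another gene, such as copies of the hemoglobin genes, so their values are uncertain.

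Genes named in the text followed a rule fixed before the data were examined: 5 genes that check the labels (Camk2a, Slc17a7, Slc32a1, Gad1 and Gad2), in each direction the 8 genes with the largest difference among those past the threshold, 12 RAS-ERK pathway genes, up to 6 members past the threshold of each RAS-related list and up to 4 of each other list by smallest p. The 8 genes needed at least 20 CPM in both libraries of the higher group, which was computed from the linear values as a share of their total; predicted genes, RIKEN clones and pseudogenes were left out. Some genes that this rule names are not reported here, and counts over gene lists include them. Htr3a, Npy, Mbp, Snap25, Xist and the Y-linked genes, and the machinery genes with large differences or at 0, were named after their values were seen. The sampling check compared each pair of libraries over tested genes with a mean above 100 estimated reads, which are linear values divided by the spacing. The median chi-square was 52 and 56.4 times that of counting error within the groups and 910 to 967 times between them. No library was therefore counted as a copy of another.

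The test was checked on simulated data with the real means of the 13619 genes, spreads after limma's moderation, and 50 changed genes per size, drawn from genes with a mean above 10. For the comparison of excitatory with inhibitory libraries, 12%, 52%, 98% and 100% of genes changed by 0.5, 1, 2 and 4 log2 units were recovered, with 8 false calls. Genes of lower values were not among the changed genes. The first version of the simulation, with unmoderated spreads and changed genes with a mean above 5, recovered 0%, 4%, 20% and 60% of genes changed by 0.5, 1, 2 and 4 log2 units, with 2 false calls; the moderated spreads and higher genes were chosen after this result. With no change, 0 of 60 random lists of 20 genes were called. The simulated genes varied independently, so this does not cover lists of correlated genes. The microglia and cytosolic ribosomal lists had estimated correlations of 0.504 and 0.553.

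Alternatives tried were median-of-ratios and upper-quartile scaling of the linear values, no filter, a minimum of 5, the replicate number as a block, a pseudocount of 0.1, leaving out the 20 highest genes and rescaling, leaving out each library in turn, and, chosen after the data were seen, only genes above 0 in all 4 libraries. Several count-based tests, a voom fit and a fold threshold test were planned for counts only and were not run.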

Results

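Total RNA was profiled from cells of the mouse brain labelled as excitatory or inhibitory neurons, in a study of ERK signalling in Noonan syndrome, a developmental disorder caused by mutations in genes of the RAS-ERK pathway. Per the labels, the excitatory libraries hold fluorescent cells positive for αCaMKII, a kinase of glutamatergic forebrain neurons, and the inhibitory libraries fluorescent cells positive for vGAT, the transporter that loads GABA into synaptic vesicles. Each of the 4 libraries was made from 100 cells picked by hand, with 2 libraries per label. The deposited value of a gene is log2(normalized reads + 1), and differences below are excitatory minus inhibitory on that scale. Between 12609 and 12798 genes were above 0 in a library. Spacing of the lowest values put the depth at about 62300000 to 74200000 reads per library. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

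Marker genes of inhibitory neurons went both with and against the labels, so excitatory and inhibitory below name libraries by their labels, and every direction is between libraries so labelled. Of 8 tested GABAergic identity genes 4 were higher in the excitatory and 1 in the inhibitory libraries, and of 14 tested interneuron subclass markers 7 and 4. Against the label, the interneuron genes Lhx6 (45.4-fold, a call lost without excitatory replicate 1 or 2, adjusted p = 0.172 and 0.148) and Sst (4.02-fold) were higher in the excitatory libraries. With it, Dlx2, Lamp5, Calb2, Htr3a and Npy were higher in the inhibitory libraries. The serotonin receptor gene Htr3a had 2.97 and 0 against 11.25 and 10.42, and lost its call without inhibitory replicate 1 (limma adjusted p = 0.0883) or inhibitory replicate 2 (0.0783). The neuropeptide gene Npy differed by -0.87 (SE 0.21, limma adjusted p = 0.0171), a call lost without excitatory replicate 2 (0.0562), inhibitory replicate 1 (0.108) or inhibitory replicate 2 (0.0965). Slc32a1, the gene of vGAT, was listed at 0 in all 4 libraries. A listed 0 was not read as absence, since of 149 genes of cell machinery that every cell uses 2 were also at 0 in all 4 libraries and 10 were at 0 in both libraries of one label with at least 5 in both of the other. One of these, Lars, the gene of a leucyl-tRNA synthetase, was at 0 in both excitatory libraries with 8.88 and 8.33 in the inhibitory ones. Values after median-of-ratios scaling, which sets the median difference of all genes near 0, are called scaled below, and differences given without mention of scaling are from the deposited values. Camk2a, the gene of αCaMKII, was 16.50 ± 0.047 (SD, n = 2) in the excitatory and 15.63 ± 0.038 in the inhibitory libraries, a 1.83-fold difference (log2 0.87, SE 0.061, limma adjusted p = 3.18e-04) that was 1.25-fold after scaling (adjusted p = 0.00677). Slc17a7, the main vesicular glutamate transporter of the cortex, was 12.13 ± 0.089 and 11.83 ± 0.23, a difference of 0.30 that did not pass (adjusted p = 0.182) and that was -0.24 after scaling (adjusted p = 0.312). Gad1, which encodes a GABA-synthesizing enzyme, was 11.04 ± 0.18 in the excitatory and 11.52 ± 0.10 in the inhibitory libraries; its difference of -0.48 did not pass (adjusted p = 0.0649) and was -1.02 after scaling, where it passed (adjusted p = 0.00768). Gad2, the gene of another such enzyme, differed by -0.08 (adjusted p = 0.824) and by -0.62 after scaling (adjusted p = 0.137).

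The libraries labelled excitatory and those labelled inhibitory differed in most of the genes tested. Of 13619 genes tested, 9777 (71.8%) passed limma's moderated test at an adjusted p of 0.05. Of these, 6122 were higher in the excitatory and 3655 in the inhibitory libraries. The median difference over all tested genes was 0.52, a 1.43-fold shift towards the excitatory libraries in the deposited values. In these values a read carried more weight in the excitatory (spacing 1.28 and 1.22) than in the inhibitory libraries (0.72 and 0.873). The shift cannot be told apart from that weighting. After scaling 8977 genes passed, 4415 higher in the excitatory and 4562 in the inhibitory libraries. The share of differing genes that were higher in the excitatory libraries was therefore 62.6% in the deposited values and 49.2% after scaling. In both scalings 8070 genes passed with the same direction and 13 with opposite directions. Pearson's correlation across genes was 0.984 between the 2 excitatory and 0.98 between the 2 inhibitory libraries, against 0.525 to 0.532 between libraries of different labels; genes are not independent replicates. Of the differing genes, 1036 were listed at 0 in both inhibitory libraries and 1058 in both excitatory libraries. Without any 1 of the 4 libraries, 6103 to 6551 genes passed: 6157 without excitatory replicate 1, 6103 without excitatory replicate 2, 6449 without inhibitory replicate 1 and 6551 without inhibitory replicate 2.

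The genes with the largest differences had high values in the libraries of one label and values at or near 0 in those of the other. Among the genes higher in the excitatory libraries, Sema3b, which encodes a secreted semaphorin, had values of 13.68 and 13.23 in the excitatory libraries and was listed at 0 in both inhibitory libraries. Trpm7, which encodes a cation channel with a kinase domain, had 13.24 and 13.03 and was likewise listed at 0 in both inhibitory libraries. Pqlc1, Rpf2 and Sytl2 were also listed at 0 in both inhibitory libraries, with excitatory values between 12.20 and 12.90, and Lrrcc1 had 12.82 and 12.24 against 0.48 and 0. Among the genes higher in the inhibitory libraries, Vav1, a guanine nucleotide exchange factor of blood cells, had 13.97 and 13.57 in the inhibitory libraries and was listed at 0 in both excitatory libraries. Fam105a, Tlk2, Capn3, Zfp869, Trip10 and Ptprc were listed at 0 in both excitatory libraries, with inhibitory values from 11.80 (Ptprc) to 13.18 (Fam105a). Zfp433 had 13.56 and 13.93 in the inhibitory libraries against 2.38 and 0. Each of these genes passed limma's test with an adjusted p of 2.85e-04 or below in the deposited values and of 2.78e-04 or below after scaling. Vav1 spans positions 57279100 to 57328031 of chromosome 17 and Sema3b positions 107597674 to 107609229 of chromosome 9 of mm10.

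Markers of glutamatergic and GABAergic neurons moved in both directions. Of 17 glutamatergic identity genes, 9 were higher in the excitatory libraries, 3 were higher in the inhibitory libraries and 5 did not pass. Adjusted over the list alone the counts were 10 and 3, and after scaling 6 and 4. Slc17a6, a vesicular glutamate transporter, had 9.08 and 8.49 in the excitatory libraries and was listed at 0 in both inhibitory libraries. The synaptic vesicle gene Sv2b was 5.72 higher in the excitatory libraries (SE 0.39, limma adjusted p = 2.98e-04) and the transcription factor gene Emx1 had 0.43 and 0 in the excitatory against 7.04 and 7.23 in the inhibitory libraries. As a list the glutamatergic genes were not shifted against other genes (camera adjusted p = 0.654). Of 16 GABAergic identity genes 8 could be tested and 5 were listed at 0 in all 4 libraries. Of the 8, 4 were higher in the excitatory libraries, 1 was higher in the inhibitory libraries and 3 did not pass, the counts adjusted over the list alone were also 4 and 1, and after scaling they were 2 and 2. The interneuron transcription factor gene Lhx6 was 5.50 higher in the excitatory libraries (SE 0.99, limma adjusted p = 0.00658), a call lost without excitatory replicate 1 (adjusted p = 0.172) or excitatory replicate 2 (0.148). Adarb2 was 2.96 higher in the excitatory libraries, a call lost without inhibitory replicate 1 (adjusted p = 0.178) or inhibitory replicate 2 (0.156). Dlx2 was listed at 0 in both excitatory libraries and had 5.05 and 5.61 in the inhibitory libraries. The camera test of the GABAergic list gave an adjusted p of 0.991; the median difference of the list was 0.29 and its mean 0.57 while the test pointed down.

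Among markers of interneuron subclasses, 7 of 14 tested genes were higher in the excitatory and 4 in the inhibitory libraries, the same counts adjusted over the list alone (5 and 4 after scaling; camera adjusted p = 0.991). The neuropeptide gene Sst was 2.01 higher (SE 0.22, limma adjusted p = 0.00129) and the cannabinoid receptor gene Cnr1 6.61 higher (SE 0.44) in the excitatory libraries. Lamp5 was listed at 0 in both excitatory libraries and had 9.75 and 9.33 in the inhibitory libraries, and Calb2, a calcium-binding protein gene, was higher in the inhibitory libraries (-5.31, SE 0.59), a call lost without excitatory replicate 1 (adjusted p = 0.0677) or excitatory replicate 2 (0.0564). Transcripts of glial cells were among the highest values in all 4 libraries, beside each of these groups: the astrocyte gene Aldoc ranked 5 in every library, while the neuronal gene Snap25 ranked between 86 and 92.

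The study concerns ERK signalling, and the genes of the RAS-ERK pathway were compared for this question. Libraries of both labels held Ptpn11, the gene of the phosphatase SHP2 that is mutated in many people with Noonan syndrome, at 12.70 ± 0.077 (SD, n = 2) in the excitatory and 12.65 ± 0.25 in the inhibitory libraries. The difference of 0.05 (SE 0.17) did not pass limma's test (adjusted p = 0.8), and it was -0.49 after scaling (adjusted p = 0.0851). The RAF kinase gene Braf was higher in the inhibitory libraries (difference -5.62, SE 0.50, adjusted p = 0.000665), as was Nf1, which encodes a GTPase-activating protein that switches RAS off (-4.79, SE 0.36, 4.05e-04). Hras (0.87, SE 0.087, 1.83-fold, adjusted p = 0.000936), Mapk3, which encodes ERK1 (1.40, SE 0.14, 2.64-fold, 0.000825), and the kinase gene Map2k2 (1.19, SE 0.16, 2.27-fold, 0.00239) were higher in the excitatory libraries. Braf, Nf1, Hras, Mapk3 and Map2k2 kept their direction and passed after scaling. The scaled folds were smaller for Hras (1.26-fold, limma adjusted p = 0.0251), Mapk3 (1.81-fold) and Map2k2 (1.56-fold, 0.0306). The scaled differences were larger for Braf (-6.15) and Nf1 (-5.32).

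**Figure D1:**
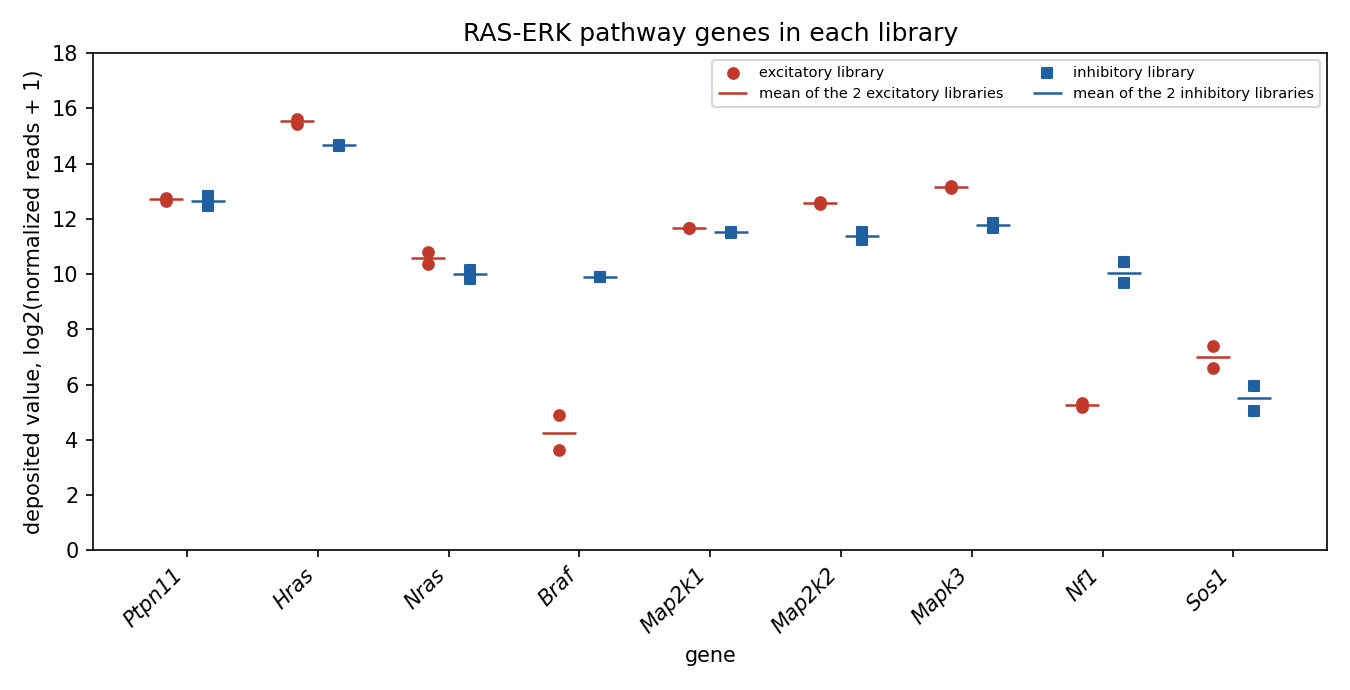
Deposited values (y axis, log2 of normalized reads + 1) of 9 RAS-ERK pathway genes (x axis) in the 2 excitatory (circles) and 2 inhibitory (squares) libraries, with lines at the mean of each group. Braf was 4.26 on average in the excitatory and 9.89 in the inhibitory libraries, while Ptpn11 was 12.70 and 12.65.

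Map2k1 (11.66 against 11.51) and Nras (10.58 against 9.98) did not pass limma's test in either scaling, with adjusted p of 0.373 and 0.0875 in the deposited values, and the difference of Map2k1 was below 0 after scaling (-0.39). Sos1, a RAS activator, was 1.5 higher in the excitatory libraries (SE 0.50, adjusted p = 0.0474), did not pass after scaling (0.154) and lost its call without any 1 library (0.124 to 0.286). Leaving out 1 library ended other calls too. Braf did not pass without inhibitory replicate 1 (adjusted p = 0.058) or inhibitory replicate 2 (0.0573), and Map2k2 without excitatory replicate 1 (0.0608) or excitatory replicate 2 (0.0644).

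Genes mutated in RASopathies, the disorders of this pathway, were split between the labels. Of 23 such genes 8 were higher in the excitatory libraries, 8 were higher in the inhibitory libraries and 7 did not pass. Adjusted over the list alone the counts were 6 and 8, and after scaling 4 and 9. Rit1, a RAS-like GTPase gene, was 1.95 higher (SE 0.11, limma adjusted p = 1.70e-04) and Rasa1, another GTPase-activating protein gene, 2.48 higher (SE 0.21) in the excitatory libraries. The camera test gave an adjusted p of 0.991, with a median difference of 0.16, a mean of -0.29 and a test that pointed down. Of 26 tested genes of the RAS-ERK cascade 13 were higher in the excitatory and 8 in the inhibitory libraries, the same counts adjusted over the list alone, and 5 did not pass; after scaling the counts were 7 and 9 (camera adjusted p = 0.991). The scaffold gene Ksr1 had 10.74 and 10.43 in the excitatory libraries and was listed at 0 in both inhibitory libraries. Araf, a RAF kinase gene, was 1.56 higher in the excitatory libraries (SE 0.10, 2.94-fold). Mknk1, a kinase gene downstream of ERK, was listed at 0 in both excitatory libraries and had 5.02 and 4.39 in the inhibitory libraries.

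Regulators above and below the cascade were split as well. Of 16 tested RAS exchange factors and GTPase-activating proteins 6 were higher in the libraries of each label (8 and 6 adjusted over the list alone, 5 and 6 after scaling; camera adjusted p = 0.991). Rasgrp3 had 3.70 and 4.11 in the excitatory against 11.29 and 11.84 in the inhibitory libraries, and Rasal3 was listed at 0 in both excitatory libraries with 7.15 and 6.57 in the inhibitory ones. Rasgrf1, a calcium-responsive exchange factor gene, was 1.76 higher (SE 0.12) and Dab2ip 1.99 higher (SE 0.19) in the excitatory libraries. Of 26 tested genes of SHP2 adaptors and receptor tyrosine kinases 12 were higher in the excitatory and 9 in the inhibitory libraries (12 and 10 adjusted over the list alone, 10 and 12 after scaling; camera adjusted p = 0.912). The insulin receptor gene Insr had 11.16 and 11.47 in the excitatory against 0.48 and 0.79 in the inhibitory libraries. Among the adaptors of the Gab family, Gab2 was listed at 0 in both inhibitory libraries (8.89 and 8.09 in the excitatory ones) and Gab3 in both excitatory libraries (10.49 and 10.05 in the inhibitory ones). Met and Frs3 were listed at 0 in both excitatory libraries as well. Sirpa, a membrane protein that binds SHP2, was higher in the inhibitory libraries (-1.41, SE 0.079, 2.67-fold).

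Genes of the ERK feedback list and immediate early genes differed strongly but not in one direction, and ERK activity itself was not measured. Of 12 tested Dusp phosphatase and Sprouty-family genes of this list 4 were higher in the excitatory and 6 in the inhibitory libraries. The counts were 4 and 6 adjusted over the list alone and 2 and 6 after scaling (camera adjusted p = 0.442). The phosphatase gene Dusp1 had 1.40 and 0.34 in the excitatory against 11.05 and 10.56 in the inhibitory libraries. Dusp14 (-3.90, SE 0.32), Dusp7 (-2.69, SE 0.30) and Spred2 (-6.93, SE 0.58) were also higher in the inhibitory libraries, where Dusp7 lost its call without inhibitory replicate 1 (limma adjusted p = 0.0554) or inhibitory replicate 2 (0.0555) and Spred2 without inhibitory replicate 1 (0.0505). Spred3 (4.97, SE 0.41) and Dusp10 (6.09, SE 0.71) were higher in the excitatory libraries, and Dusp10 lost its call without excitatory replicate 1 (0.0932) or excitatory replicate 2 (0.0876). Of 15 tested immediate early genes, which neurons switch on after activity, 5 were higher in the excitatory and 8 in the inhibitory libraries, in the deposited values and adjusted over the list alone (5 and 9 after scaling; camera adjusted p = 0.442). Fos had 5.73 and 4.82 in the excitatory against 13.32 and 12.89 in the inhibitory libraries, and Junb was lower in the excitatory libraries as well (-5.19, SE 0.31). Nr4a1 and Fosl2 went the other way and were listed at 0 in both inhibitory libraries, with excitatory values of 9.19 and 8.73 for Nr4a1 and 9.04 and 9.93 for Fosl2.

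**Figure D2:**
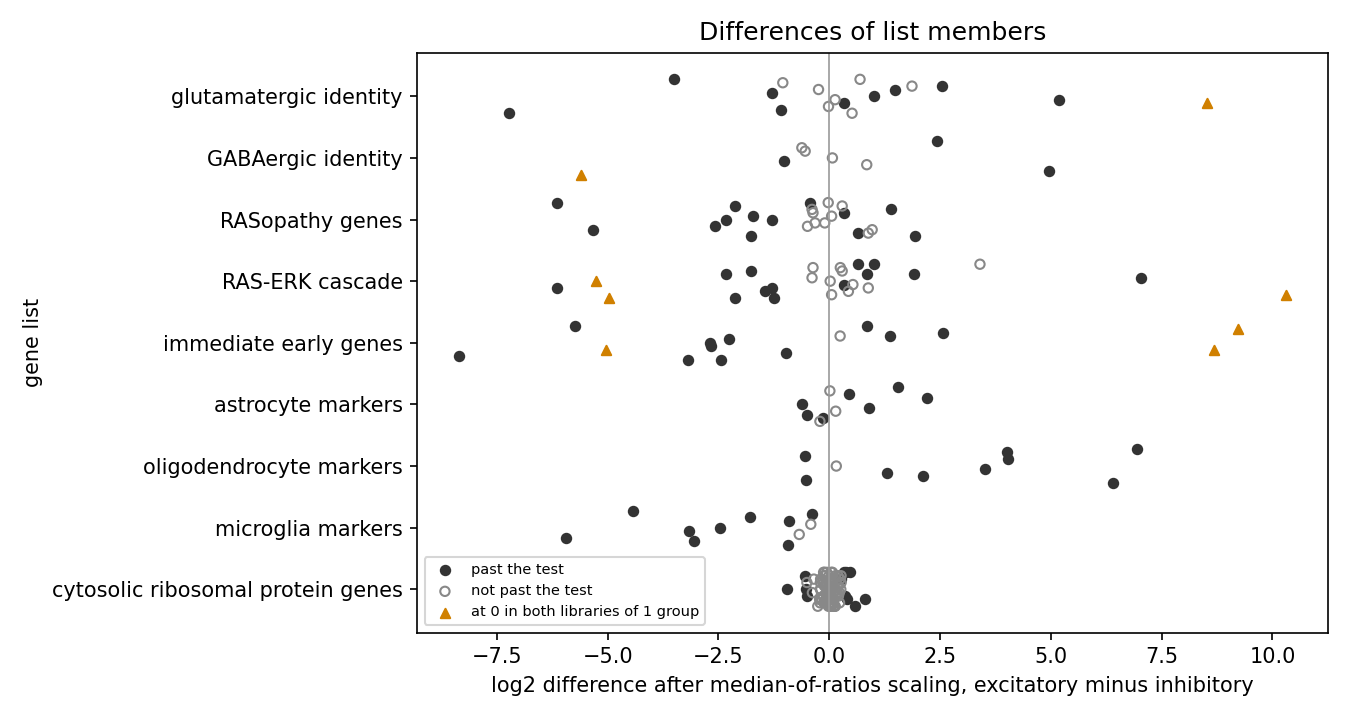
Differences of the tested members of 9 gene lists (y axis) as log2 excitatory minus inhibitory after median-of-ratios scaling (x axis); filled points passed limma's test after scaling, open points did not, and triangles are genes at 0 in both libraries of 1 group. Members of the RASopathy and RAS-ERK lists lie on both sides of 0, with 4 and 9 RASopathy genes past the test.

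Markers of glial cells differed between the labels gene by gene, and of the microglia, oligodendrocyte and astrocyte lists camera called the microglia list. Of 11 microglia markers 6 were higher in the inhibitory libraries and none in the excitatory libraries, and 5 did not pass (0 and 6 adjusted over the list alone; 0 and 9 after scaling). The protease gene Ctss (-1.26, SE 0.079, 2.39-fold), Aif1 (-3.89, SE 0.21) and Tmem119 (-5.41, SE 0.30) were among them. The list was lower in the excitatory libraries by camera (adjusted p = 0.0145), a call that ended with an estimated correlation (adjusted p = 0.951 with an estimated correlation), without excitatory replicate 1 (0.0992) and without inhibitory replicate 1 (0.116). Of 10 oligodendrocyte markers 7 were higher in the excitatory libraries and none in the inhibitory libraries (the same counts adjusted over the list alone; 7 and 2 after scaling; camera adjusted p = 0.115). The myelin genes Cnp (1.84, SE 0.11), Mal (4.05, SE 0.18) and Ermn (4.58, SE 0.17) were among them. Mbp, the myelin basic protein gene, had the value 21.331 in all 4 libraries, the highest of each, for a reason that could not be settled. Its deposited values give no comparison, yet it counts among the 10 markers in the list counts and list tests. Of 10 astrocyte markers 8 were higher in the excitatory libraries (8 adjusted over the list alone), but after scaling 4 were higher and 3 lower (camera adjusted p = 0.115). The water channel gene Aqp4 was 2.75 higher (SE 0.078, 6.74-fold; 2.21 and 4.63-fold after scaling) and Aldh1l1 2.10 higher (1.55 after scaling), and both passed in both scalings. Aldoc (0.69) and the glutamate transporter gene Slc1a2 (0.56) did not pass after scaling (limma adjusted p = 0.259 and 0.737), and lost their calls without excitatory replicate 1 (0.0816 and 0.0713) or excitatory replicate 2 (0.0823 and 0.0616).

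Genes of glutamate and GABA receptors and of ion channels differed in both directions, and none of these lists passed camera. Of 21 tested glutamate receptor genes 14 were higher in the excitatory and 3 in the inhibitory libraries (14 and 3 adjusted over the list alone, 11 and 3 after scaling; camera adjusted p = 0.274). Grm8 was listed at 0 in both inhibitory libraries, with excitatory values of 8.66 and 8.97. The kainate receptor gene Grik2 had 1.40 and 1.32 in the excitatory against 12.10 and 11.52 in the inhibitory libraries, and the NMDA receptor gene Grin3a was also higher in the inhibitory libraries (-6.26, SE 0.30). Of 13 tested GABA receptor genes 8 were higher in the excitatory and 1 in the inhibitory libraries (8 and 1 adjusted over the list alone, 6 and 3 after scaling; camera adjusted p = 0.442). Gabrb2 (4.81, SE 0.26), Gabbr2 (9.0, SE 0.64) and Gabra5 (3.30, SE 0.24) were higher in the excitatory libraries, while Gabra4 was listed at 0 in both excitatory libraries and had 9.34 and 9.89 in the inhibitory ones.

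Of 30 tested voltage-gated potassium, sodium and HCN channel genes 13 were higher in the excitatory and 7 in the inhibitory libraries (13 and 7 adjusted over the list alone, 10 and 10 after scaling; camera adjusted p = 0.991). The sodium channel gene Scn8a was 3.17 higher in the excitatory libraries (SE 0.17), while Scn1a had 1.98 and 1.90 in the excitatory against 9.17 and 8.90 in the inhibitory libraries. Hcn3 was listed at 0 in both inhibitory libraries (10.06 and 9.67 in the excitatory ones) and the potassium channel gene Kcnc2 was higher in the inhibitory libraries (-4.48, SE 0.31). Of 23 calcium-calmodulin plasticity genes 12 were higher in the excitatory and 3 in the inhibitory libraries (12 and 3 adjusted over the list alone, 6 and 7 after scaling; camera adjusted p = 0.59). Prkcb (1.15, SE 0.083, 2.22-fold), the postsynaptic scaffold gene Shank2 (1.81, SE 0.18, 3.52-fold) and Dlg4, which encodes a postsynaptic density protein (3.27, SE 0.33), were higher in the excitatory libraries and passed after scaling too. Dlg4 lost its call without excitatory replicate 1 (limma adjusted p = 0.0584) or excitatory replicate 2 (0.0512).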

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

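Tests with only genes above 0 in all 4 libraries were chosen after the data were seen; the other alternatives were planned. Without 1 library, 6103 to 6551 genes differed, 3530 to 4241 higher in the excitatory and 2310 to 2627 in the inhibitory libraries, with fewer samples in the fit. Among genes above 0 in all 4 libraries, 2259 were higher in the inhibitory libraries, with fewer genes tested. Under every other setting the counts stayed within 1.5 times of 9777, 6122 and 3655: 8947 genes with a minimum of 5 and 9633 without a filter differed. With the replicate block 9782 genes differed. The replicate deviations of the 2 groups correlated at -0.00193 over genes, so no deviation shared by replicate number was seen. That value cannot show whether libraries of the same number shared an animal or a preparation. The block changed the call of 1 named gene, Flt1 (limma adjusted p = 0.0591). Within the groups the median chi-square between libraries was 52 and 56.4 times that of counting error, over genes with a mean above 100 estimated reads. Whether depth limits the calls at low values was not tested.

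By fry, which tests whether a list's genes move one way and compares the list with no other genes, 14 of 25 lists passed. In 10 of these fry pointed to higher values in the excitatory libraries: glutamatergic (adjusted p = 0.0187), striatal (0.0372), RAS-ERK (0.0228), glutamate receptor (0.00869), GABA receptor (0.0156), calcium-calmodulin (0.0322), astrocyte (0.00712), oligodendrocyte (0.00951), oligodendrocyte precursor (5.76e-04) and endothelial (0.00115) lists. In the other 4 it pointed to lower values there: ERK feedback (0.00951), microglia (0.0171), ependymal (0.00951) and red blood cell (0.00971) lists. Such a direction does not mean that the members moved together. Genes higher in the excitatory and in the inhibitory libraries numbered 3 and 2 for striatal, 2 and 2 for precursor and 1 and 1 for ependymal markers. Since 71.8% of all tested genes differed, passing a test that uses no other genes says little about a list. Of the 14, camera called microglia markers, and red blood cell markers with a minimum of 5 (0.0117), and no other under any setting run. That minimum removed Alas2, the 1 red blood cell marker higher in the excitatory libraries. With an estimated correlation, run without that minimum, camera called neither the microglia nor the red blood cell list (adjusted p = 0.951 for both). The ribosomal list, which camera called, did not pass by fry (0.0673), nor by camera with an estimated correlation (adjusted p = 0.992). Of the list tests, 42 uncalled ones over 11 lists changed sign and stayed uncalled, and the cause was not tested. Their adjusted p were, for the GABAergic list, 0.995 without a filter, 1 with the replicate block, 0.746 with genes above 0 in all 4 libraries and 0.913 to 0.999 without 1 library. The RASopathy list gave 0.31 by fry and 0.913 to 0.989 without 1 library, and the RAS-ERK cascade 0.913 to 0.999. With a minimum of 5 they were 0.828 for interneuron subclass markers, 0.996 for cortical layer markers, 0.822 for oligodendrocyte precursors and 0.938 for heat shock genes. With median-of-ratios scaling, striatal, precursor and heat shock lists gave 0.954, with upper-quartile scaling 0.933, 0.96 and 0.933, and without the 20 highest genes 0.947, 0.95 and 0.947. Without a filter striatal markers gave 0.989. With pseudocount 0.1 striatal, cortical and precursor lists gave 0.971, and with the replicate block the cortical and heat shock lists gave 1. With genes above 0 in all 4 libraries cortical, SHP2 adaptor and heat shock lists gave 0.746. By fry SHP2 adaptors gave 0.688 and immediate early genes 0.224, and the striatal and precursor calls by fry were opposite in sign to camera. Without 1 library the range was 0.973 to 0.999 for striatal, 0.926 to 0.999 for cortical and 0.913 to 0.999 for precursor markers and voltage-gated channels; these ranges cover all 4 fits, of which some kept their sign.

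Of 120 genes chosen by the naming rule and followed through the alternatives, 114 passed, and 18 of these lost the call without 1 library or more. Of the genes that changed sign, only Map2k1 without the 20 highest genes passed (-0.42, adjusted p = 0.0499). The others, none past the test in either fit, were Map2k1 (-0.389 with median-of-ratios, -0.386 with upper-quartile scaling), Ptpn11 (-0.491, -0.488 and, without the 20 highest genes, -0.520), and Slc17a7 (-0.242, -0.239, -0.272), in the same order. Without 1 library Ptpn11 was -0.127 to 0.231 and Gad2 -0.404 to 0.252. The cause was not tested.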

Other observations

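The tests on the ratio of splits and on glial markers were chosen after the result was seen, including a second test of the neuron share that was added when the first decided nothing; the test on genes that differ by at least 5 log2 units was added after the first test on machinery genes gave a count of 0, and the one on genes of at least 5 after machinery genes at 0 had been seen.

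Markers of brain regions were split between the labels. Of 10 hippocampal markers 3 were higher in the libraries of each label (2 and 3 adjusted over the list alone and after scaling; camera adjusted p = 0.991): Spink8 was listed at 0 in both inhibitory libraries (7.87 and 8.45 in the excitatory ones), Wfs1 was 1.72 higher in the excitatory libraries, and Zbtb20 (-3.69) and Dsp (-8.64) were higher in the inhibitory libraries. Wfs1 lost its call without inhibitory replicate 1 (limma adjusted p = 0.0598) or inhibitory replicate 2 (0.0638), and Zbtb20 without inhibitory replicate 1 (0.052). Of 11 cortical layer markers 5 were higher in the excitatory and 4 in the inhibitory libraries in both scalings and adjusted over the list alone (camera adjusted p = 0.991), with Cux1 (2.32), Cux2 (7.42) and Etv1 (2.08) higher in the excitatory and Rorb (-3.19) in the inhibitory libraries. All 5 tested striatal markers differed, 3 higher in the excitatory libraries (Pdyn 4.64) and 2 in the inhibitory libraries (Isl1 -8.16, Pde10a -5.71), in both scalings and adjusted over the list alone; the median of the list was 1.56 and its mean -0.67 (camera adjusted p = 0.991, pointing down). Slc6a4, the serotonin transporter gene, was the 1 testable gene of the list of other transmitter neurons and was listed at 0 in both excitatory libraries, with 6.56 and 7.83 in the inhibitory ones.

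Transcripts of blood, vessel and stress genes also differed. Of 5 red blood cell markers 4 were higher in the inhibitory and 1 in the excitatory libraries, adjusted over the list alone as well (camera adjusted p = 0.115). With a minimum of 5 the list passed as lower in the excitatory libraries (camera adjusted p = 0.0117). That minimum removed Alas2 (4.17 and 4.46 against 0 and 0), the 1 marker higher in the excitatory libraries. The call therefore rests on markers of 1 direction. Without that minimum, camera with an estimated correlation gave an adjusted p of 0.951. The hemoglobin gene Hbb-bs was listed at 0 in both excitatory libraries and had 9.86 and 9.37 in the inhibitory ones. Hba-a1 lost its call without inhibitory replicate 1 or inhibitory replicate 2. The 3 testable endothelial and mural markers were higher in the excitatory libraries, adjusted over the list alone as well (camera adjusted p = 0.274), with Rgs5 at 9.80 and 10.04 against 1.83 and 1.79; Flt1 lost its call without inhibitory replicate 1 (0.0807) or inhibitory replicate 2 (0.0798). Oligodendrocyte precursor markers were split, 2 and 2 of 5 and adjusted over the list alone the same (camera adjusted p = 0.991, median 0.36, mean 0.79, pointing down): Pdgfra was listed at 0 in both excitatory libraries (10.84 and 11.50 in the inhibitory ones), while C1ql1 and Gpr17 were listed at 0 in both inhibitory libraries. Of 3 ependymal and choroid plexus markers Kl was higher in the excitatory and Ccdc153 in the inhibitory libraries, adjusted over the list alone as well (camera adjusted p = 0.991), and Kl lost its call without excitatory replicate 1 (0.0594) or excitatory replicate 2 (0.0686). Of 10 heat shock and dissociation stress genes 6 were higher in the excitatory and 3 in the inhibitory libraries, adjusted over the list alone the same (3 and 4 after scaling; camera adjusted p = 0.991): Hspa1a had 1.98 and 1.90 against 9.97 and 9.52, and Hspd1 was 2.98 higher in the excitatory libraries. Of 81 tested cytosolic ribosomal protein genes 54 were higher in the excitatory libraries and 27 did not pass, adjusted over the list alone the same, but after scaling 8 were higher and 4 lower. The camera call (adjusted p = 0.00309) ended after scaling (0.954), without excitatory replicate 1 (0.089) and with an estimated correlation (adjusted p = 0.992 with an estimated correlation).

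A first pattern is that 229 of 6716 genes (3.41%) with at least 10 in both libraries of a label were at 0 in both libraries of the other. Random loss in each library on its own does not account for it: genes at 0 in 1 library and at 10 or more in the other numbered 5 and 0 within the groups and 378 to 407 between them, a ratio of 0.00635. Of 113 genes of cell machinery that every cell uses, 0 were split this way, where random lists of like level gave a median of 2 and a 95% range of 0 to 6, so that count does not decide between a cell type difference, which it is consistent with, and loss of transcripts from a pool of cells or cDNA shared by both libraries of a group, which cannot be told apart because 0 lies within that range. A second test, on differences of at least 5 log2 units, found 6 machinery genes (5.31%, against 13.7% of all 6716 genes), at the lower end of the random range of 6 to 18 (median 12; 4.55% of lists had as few): Cars with 11.58 and 12.32 against 1.5 and 0, Exosc10 with 12.34 and 12.36 against 0 and 2.38, Exosc8 with 12.28 and 11.58 against 6.68 and 6.71, Nup153 with 11.94 and 11.59 against 6.00 and 5.99, Cops2 with 7.02 and 6.30 against 13.83 and 14.45 and Gtf2h3 with 2.39 and 1.32 against 10.75 and 10.85, of which Exosc8, Nup153 and Cops2 stayed well above 0 in the lower group. In a further test, on genes of at least 5 in one group, 10 of 143 machinery genes (6.99%) were at 0 in both libraries of the other group, within the range of 4 to 15 (median 9) of random lists of like level, among them Eif2b1 with 10.68 and 9.76 against 0 and 0 and Lars with 0 and 0 against 8.88 and 8.33. Genes that every cell uses should not be so split, so cell type expression alone is an unlikely account of the machinery genes at 0 in one group. Neither count decides this for large differences and zeros in general, although both were above a bound of 3 genes. The count of 6 lay at the lower end of the random range. The test that gave 10 was chosen after machinery genes at 0 had been seen, so its count restates what prompted it. Loss before the libraries were made stays open as well.

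A second pattern is that glial transcripts stood among the highest values. Apoe ranked 2 or 3 and Aldoc 5 in every library, against 100 to 124 for Camk2a. Of 31 astrocyte, oligodendrocyte and microglia markers 30 (96.8%) were above 0 in all 4 libraries, which may reflect glial cells or glial RNA taken up with the hand-picked cells, although picking by fluorescence should leave most of them out; neurons express some of these genes as well. For a lower share of neurons in one group as the cause of the group difference in glial markers, the first test, the microglia median after scaling (-1.8), was set against a condition that both the microglia and the oligodendrocyte lists pass camera, which the oligodendrocyte list (adjusted p = 0.115) did not meet, so it decided nothing. The second test, added after this, compared the oligodendrocyte mean (2.74) with the microglia mean (-2.20), a difference of 4.94. An exact permutation over the 10 marker genes (Mbp among them) and 11 marker genes gave a two-sided p of 1.70e-05, but these genes are not independent. A lower neuron share with an unchanged mix of glia would move both lists one way, so the opposite signs argue against that case. A lower neuron share together with a different mix of glia need not do so, and the test cannot decide on it.

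A further pattern is Xist, the transcript of the inactive X chromosome, at 2.97 and 2.31 in the excitatory and 10.32 and 10.04 in the inhibitory libraries of mice labelled male. RNA of female cells might account for it, and 2 of 4 Y-linked genes were lower in both inhibitory libraries, Ddx3y (12.02 and 12.07 against 8.64 and 9.41) and Eif2s3y (6.73 and 6.49 against 0 and 0), while Kdm5d and Uty were listed at 0 in all 4 libraries. With Kdm5d and Uty at 0 throughout, the planned bound of 3 lower genes could not be reached, so that test could not favour RNA of female cells. The bound in the other direction was not met either. Xist and the Y-linked genes above 0 went the way that RNA of female cells would move them, but it cannot be told apart from other causes.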
